A study of Homo sapiens with 440 samples.

How the data were processed

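Transcript levels of 53 human tumour cell lines were measured on 440 Affymetrix arrays. Per the labels' protocols, the cells were grown in RPMI-1640 with serum and L-glutamine and pre-plated for 24 h, drugs were dissolved in DMSO (0.25% in the culture), RNA was isolated with Qiagen RNeasy kits, only RNA that passed the laboratory's quality score was used, and samples were labelled with biotin by an Affymetrix kit. The deposited values are log2 signals, 1 per probe set, summarised by the authors. The values themselves show the log2 scale, with a range of 3.06 to 13.98, and nearly the same distribution on each array, with array means between 6.29 and 6.46. The summarisation, background correction and normalisation are not given in the sources used here. A genome build does not enter, because no positions were used.

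The array held 22277 probe sets. The platform's annotation gave 1 gene symbol to 19070 of them and several to 1043, 2164 were not listed, and 62 were control probe sets. Each of 11963 genes was read by its probe set with the highest mean over all arrays, of those with 1 symbol, and 4310 genes had more than 1 such probe set. At 5000 nM and 24 h, 170 genes had probe sets called in opposite directions, none of them named in the text. Probe sets with several symbols or none were tested apart. No filter on low signals was applied in the tests reported first.

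Arrays were grouped by line, dose and time as labelled. The lines are the replicates, since a line has at most 1 array at a dose and time and nothing says that its arrays come from separate experiments. Each comparison took the difference of log2 values within each line and tested its mean over lines with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), at a Benjamini-Hochberg adjusted p under 0.05 over all genes. The spread is therefore that of the response between lines. Comparisons were 1000 nM and 5000 nM against 0 nM, 5000 nM against 1000 nM, the difference of the 5000 nM effect between times, 0 nM cultures at 6 h and 24 h against 2 h, and an F test of tissue label on the 24 h differences. Counts are also given for a mean change of at least 1.5-fold and for genes that moved the same way in at least 80% of lines.

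Scores of 27 gene lists were the mean log2 difference over a list's measured genes in each line, tested by sign-flip permutation over lines (100000 draws, 2-sided) and adjusted over 162 tests. Beside them stands limma's camera, with a preset correlation of 0.01 and with an estimated one. Camera sets a list against the other genes, while the permutation asks whether the score differs from 0. Lines are the units of the permutation, so correlation between genes does not enter its p. A list can therefore pass the permutation and not camera without a conflict. Differences of list scores between tissue labels were tested by permutation. Baseline levels were related to the response with Pearson's r and Spearman's rho, each with a permutation p, adjusted over 16 relations. Genes shared between doses were set against independent lists, against simulated unchanged groups with shared controls (100 simulations) and against separate lines for each dose (20 splits). The list genes, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest rises and falls at 5000 nM and 24 h, and the 5 largest of each in the other comparisons, among called genes moved the same way in at least 80% of lines. It also names up to 4 genes of a list by p, the 8 genes with the smallest p in the tissue test, and DNMT1, DNMT3A, DNMT3B, TRDMT1, UCK1, UCK2, SLC29A1, CDA, RRM2, CDKN1A and MDM2.

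The pairing of arrays with line labels was checked with the group means removed. Each array was matched to the line label with the closest median profile and to its nearest array. Of 440 arrays, 417 matched their own line label on both checks. The other 23, of 9 line labels, failed at least 1 check (20 on the profile, 9 on the nearest array) and are called doubted arrays. An array was compared with the other arrays of its label, so a line with a wrong name on all its arrays would pass. The GAPDH control probe sets at the 3' and 5' ends of the transcript gave a measure of RNA integrity, and 30 arrays had a 3' signal more than 1 above the 5' signal on the log2 scale. These arrays were used in the comparisons, and comparisons without them, and with the 3' to 5' signal as a covariate, were added after the data were seen. The tests were run on simulated data, with changes in 200 genes added to sign-flipped differences. In these data the error of each gene's mean was drawn independently of the other genes. With 39 lines, 6% of the genes changed by 0.1 were called, 76% at 0.25, 96% at 0.5 and 100% at 1, with 0 false calls. With 50 lines at 2 h the shares were 12%, 82%, 98% and 100%, with 7 false calls (4.58%). False calls that arise when many genes move together were therefore not measured by this simulation.

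Alternatives tried were quantile normalisation, centring each array on its median, the mean of a gene's probe sets, the genes with a mean level above the median gene, no pairing by line, all 3 doses in a fit with the line as replicate block, eBayes with a trend and robust prior, only lines with all 9 arrays, each tissue label left out in turn, an adjusted p under 0.01, list medians, camera, and a baseline from 0 nM at 6 h. Tables were handled with data.table (version 1.17.8), and figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes of the sex chromosomes that could tell a donor's sex were left out of every named list.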

Results

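Transcript levels were measured on 440 Affymetrix arrays from 53 human tumour cell lines of the NCI-60 panel, a set of lines kept for screening anticancer agents. The lines were treated with azacytidine, a cytidine analogue that is built into RNA and DNA and that traps DNA methyltransferases, or with the solvent alone (0 nM). At 2 h there were 52 arrays at 0 nM, 50 at 1000 nM and 50 at 5000 nM. At 6 h there were 53, 51 and 47 arrays, and at 24 h there were 44, 47 and 46. A line had at most 1 array at a dose and time, 38 lines had all 9 arrays, and each line was compared with its own 0 nM array. The lines carried 9 tissue labels: Breast (6 lines), CNS (6), Colon (6), Leukemia (5), Lung (7), Melanoma (9), Ovarian (5), Prostate (2) and Renal (7). The deposited log2 signals ranged from 3.06 to 13.98, and the medians of the arrays lay between 5.32 and 5.73. An array has no read depth, so the number of lines limits the precision. All changes below are log2 changes against 0 nM unless another reference is named, with the SD over lines.

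The comparison of 5000 nM with 0 nM at 24 h asked which transcripts had responded to the higher dose by the last time. Genes of the stress and amino acid response were among the largest rises, and genes of cholesterol synthesis among the largest falls. TRIB3, a pseudokinase induced by the transcription factor ATF4, rose by 2.68 ± 1.14 (SD, n = 39), in 39 lines (adjusted p = 1.14e-15), from 8.78 to 11.46. ATF3 and DDIT3, stress-induced transcription factors, rose by 2.68 ± 1.26 (38 of 39 lines) and 2.35 ± 1.06 (37 of 39 lines). NIBAN1, a regulator of translation under stress, rose by 2.73 ± 1.67 (36 of 39 lines), and ASNS, which makes asparagine, by 2.17 ± 1.06 (37 of 39 lines). The other genes among the 10 with the largest rises were PCK2 at 2.05, PPP1R15A at 1.96, UPP1 at 1.86, SERPINB8 at 1.85 and CHAC1 at 1.81, with SDs between 0.93 and 1.29. INSIG1, which holds back the activation of sterol synthesis and is itself induced by it, fell by 1.92 ± 0.90 (SD, n = 39), in 38 lines (adjusted p = 9.3e-15), from 10.00 to 8.08. ACAT2, a thiolase of sterol synthesis, fell by 1.74 ± 0.73 (38 of 39 lines), and SCD, a fatty acid desaturase, fell by 1.64 ± 0.86 (39 of 39 lines). CYB5A, an electron carrier of desaturases, fell by 1.57 ± 0.69 (39 of 39 lines), ID1, an inhibitor of differentiation factors, fell by 1.51 ± 1.07 (37 of 39 lines), and E2F8, a cell cycle repressor, fell by 1.42 ± 0.92 (36 of 39 lines). NREP fell by 1.43, DHCR7 fell by 1.41, LSS fell by 1.32 and HMGN5 fell by 1.27, with SDs between 0.64 and 1.08. Of 11963 genes tested, limma called 5790, of which 2952 rose and 2838 fell. A mean change of at least 1.5-fold was reached by 854 of them, 432 up and 422 down, and 2530 moved the same way in at least 80% of lines. Without the 23 doubted arrays, 5575 genes were called over 34 lines, 5430 of them shared. The 3' to 5' signal, a mark of RNA integrity, was higher at 5000 nM by a mean of 0.11 (median 0.16, higher in 32 of 39 lines, adjusted p = 0.00714). With it as a covariate 5073 genes were called, 4821 of them shared and in the same direction.

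DNMT1, the methyltransferase that copies DNA methylation after replication and a target of azacytidine, fell by 0.41 ± 0.31 (SD, n = 39), in 36 lines (adjusted p = 5.07e-09), from 10.71 to 10.30. Its paralogues DNMT3A (0.026, adjusted p = 0.702) and DNMT3B (0.038, adjusted p = 0.769) and the tRNA methyltransferase TRDMT1 (-0.11, adjusted p = 0.183) did not pass the threshold. Nor did SLC29A1 (-0.079, adjusted p = 0.569), a nucleoside carrier. RRM2, a subunit of the ribonucleotide reductase that azacytidine metabolites act on, fell by 0.86 ± 0.81 (SD, n = 39), in 36 lines (adjusted p = 1.76e-07). CDA, which deaminates cytidine analogues, fell by 0.36 ± 0.76 (SD, n = 39), in 28 lines (adjusted p = 0.0092). The cell cycle inhibitor CDKN1A rose by 0.65 ± 0.76 (SD, n = 39), in 32 lines (adjusted p = 9.83e-06). MDM2, induced like CDKN1A by p53, did not pass at 0.045 ± 0.36 (n = 39, higher in 20 lines, adjusted p = 0.544). The kinases UCK1 and UCK2, which activate azacytidine, were not read by a probe set with 1 gene symbol.

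The gene list scores at 5000 nM and 24 h asked which gene groups moved together. The ATF4 and amino acid response list rose by 1.60 ± 0.63 (39 of 39 lines, adjusted p = 8.1e-05), adjusted p = 0.054 with an estimated correlation. Its scores reached down to 0.061 among lines labelled Renal and 0.080 among lines labelled Melanoma. Both labels hold a line whose arrays at 24 h are all doubted arrays, and 34 lines remained without doubted arrays. Of its 14 genes, 14 rose over all genes tested and 14 adjusted over the list alone. Its member SLC7A11, a cystine carrier, rose by 1.74 ± 1.11 (39 of 39 lines), and SLC3A2, its partner subunit, by 1.58 ± 0.67 (38 of 39 lines). The cholesterol synthesis list fell by 0.89 ± 0.40 (38 of 39 lines, adjusted p = 8.1e-05), adjusted p = 0.137 with an estimated correlation. Of its 12 genes, 10 fell, with 10 adjusted over the list alone. Among them IDI1, an isomerase of isoprenoid synthesis, fell by 1.18 ± 0.50 (37 of 39 lines). The S phase and E2F targets fell by 0.59 ± 0.52 (33 of 39 lines, adjusted p = 8.1e-05), adjusted p = 0.586 with an estimated correlation. Of 21 genes, 20 fell, with 20 adjusted over the list alone. TYMS, which makes thymidylate, fell by 1.17 ± 0.87 (38 of 39 lines), TK1, a thymidine kinase, fell by 1.11 ± 0.55 (37 of 39 lines), and PCNA, the sliding clamp of DNA replication, fell by 0.66 ± 0.47 (36 of 39 lines). The mitotic genes fell by 0.31 ± 0.51 (29 of 39 lines, adjusted p = 0.00241), adjusted p = 0.819 with an estimated correlation, with 15 of 22 genes down, KIF20A among them by 1.15 ± 0.81 (38 of 39 lines), and 15 adjusted over the list alone. The NRF2 targets, an antioxidant programme, rose by 0.51 ± 0.48 (34 of 39 lines, adjusted p = 8.1e-05), adjusted p = 0.729 with an estimated correlation, with 6 of 10 genes up and 6 adjusted over the list alone. The ribosome biogenesis list rose by 0.29 ± 0.30 (33 of 39 lines, adjusted p = 8.1e-05), adjusted p = 0.742 with an estimated correlation, with 11 of 14 genes up and 11 adjusted over the list alone, and the nucleolar methyltransferase NOP2 rose by 0.83 ± 0.46 (37 of 39 lines). The metallothioneins, metal-binding proteins, fell by 0.31 ± 0.36 (31 of 39 lines, adjusted p = 0.000147), adjusted p = 0.731 with an estimated correlation, with 5 of 7 genes down and 5 adjusted over the list alone.

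With the 3' to 5' signal as a covariate the ATF4 score was 1.47 (adjusted p = 1.22e-13), the cholesterol synthesis score was -0.88 (adjusted p = 2.15e-12) and the S phase score was -0.54 (adjusted p = 2.26e-05). The calls of 4 lists were lost with it: the heat shock proteins (-0.12, adjusted p = 0.0599), MHC class I (0.10, adjusted p = 0.0914), the cancer-testis antigens (0.029, adjusted p = 0.42) and the melanocytic markers (-0.19, adjusted p = 0.165). Smaller list scores passed the permutation test at 5000 nM and 24 h, and none of them passed camera with an estimated correlation. The p53 targets rose by 0.18 ± 0.21 (30 of 39 lines, adjusted p = 0.000147), adjusted p = 0.836 with an estimated correlation. Of 19 genes 7 rose and 5 fell, with 8 up and 5 down adjusted over the list alone. Their members went both ways: GADD45A, a growth arrest gene, rose by 1.34 ± 0.92 (38 of 39 lines) and the death receptor TNFRSF10B by 1.14 ± 0.68 (38 of 39 lines), while the cyclin CCNG1 fell by 1.12 ± 0.56 (39 of 39 lines). The immediate early genes rose by 0.28 ± 0.41 (30 of 39 lines, adjusted p = 0.000463), adjusted p = 0.752 with an estimated correlation, with JUN at 1.18, and the BCL2 family rose by 0.16 ± 0.19 (27 of 39 lines, adjusted p = 8.1e-05), adjusted p = 0.819 with an estimated correlation, with the death promoter PMAIP1 at 1.22. MHC class I presentation rose by 0.093 ± 0.23 (28 of 39 lines, adjusted p = 0.0431), adjusted p = 0.836 with an estimated correlation, with HLA-E, a ligand of natural killer cell receptors, at 0.61. The cancer-testis antigens, germline genes often held silent by methylation, rose by 0.059 ± 0.14 (24 of 39 lines, adjusted p = 0.0366), adjusted p = 0.836 with an estimated correlation, with 5 of 15 genes up, MAGEB2 at 0.47, and PRAME down by -0.44. The genes often silenced by promoter methylation in tumours fell by 0.13 ± 0.27 (26 of 39 lines, adjusted p = 0.0138), adjusted p = 0.818 with an estimated correlation, although RASSF1, a tumour suppressor on that list, rose by 1.38 ± 0.71 (36 of 39 lines). The DNA methylation machinery fell by 0.088 ± 0.12 (29 of 39 lines, adjusted p = 0.000249), adjusted p = 0.819 with an estimated correlation, with HELLS, a chromatin remodeller, down by -0.94. Cytidine uptake and activation fell by 0.25 ± 0.22 (33 of 39 lines, adjusted p = 8.1e-05), adjusted p = 0.586 with an estimated correlation, the heat shock proteins by 0.18 ± 0.28 (28 of 39 lines, adjusted p = 0.000993), adjusted p = 0.836 with an estimated correlation, and the mesenchymal markers by 0.32 ± 0.49 (35 of 39 lines, adjusted p = 0.00106), adjusted p = 0.814 with an estimated correlation. The imprinted genes fell by 0.15 ± 0.26 (28 of 39 lines, adjusted p = 0.0028), adjusted p = 0.819 with an estimated correlation, while the median of their members was 0.00042. The melanocytic markers fell by 0.22 ± 0.53 (22 of 39 lines, adjusted p = 0.0247), adjusted p = 0.819 with an estimated correlation, and the haematopoietic markers by 0.14 ± 0.19 (31 of 39 lines, adjusted p = 0.000249), adjusted p = 0.819 with an estimated correlation.

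Of 27 lists, 7 did not pass at 5000 nM and 24 h. They were the epithelial markers (-0.14, adjusted p = 0.0528), the interferon-stimulated genes (-0.081, adjusted p = 0.361), hypoxia and glycolysis (-0.050, adjusted p = 0.344), the endoplasmic reticulum unfolded protein response (-0.041, adjusted p = 0.561), the cytosolic ribosomal proteins (0.0081, adjusted p = 0.442), the histone genes (0.023, adjusted p = 0.937) and the NF-kappa-B and inflammatory genes (0.19, adjusted p = 0.0618). Some members of these lists changed in opposite directions: IRF7, an interferon regulator, rose by 0.61 and IFIT1, an interferon-induced RNA binder, fell by 0.79. XBP1, a regulator of the unfolded protein response, rose by 1.15 and the chaperone CALR fell by 0.93. The growth factor VEGFA rose by 1.24 and PGK1, a glycolytic enzyme, fell by 0.35. For the unfolded protein response the median of the members was 0.073, opposite in sign to the mean. Of the 20 lists that passed, 8 rose and 12 fell, and 7 also passed limma's camera with the preset correlation: ATF4, cholesterol synthesis, S phase, mitotic genes, metallothioneins, ribosome biogenesis and NRF2. With an estimated correlation, the lowest adjusted p of camera was 0.0540 and the highest was 0.964. The smallest permutation p, 1e-05, is the smallest they can give.

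**Figure D1:**
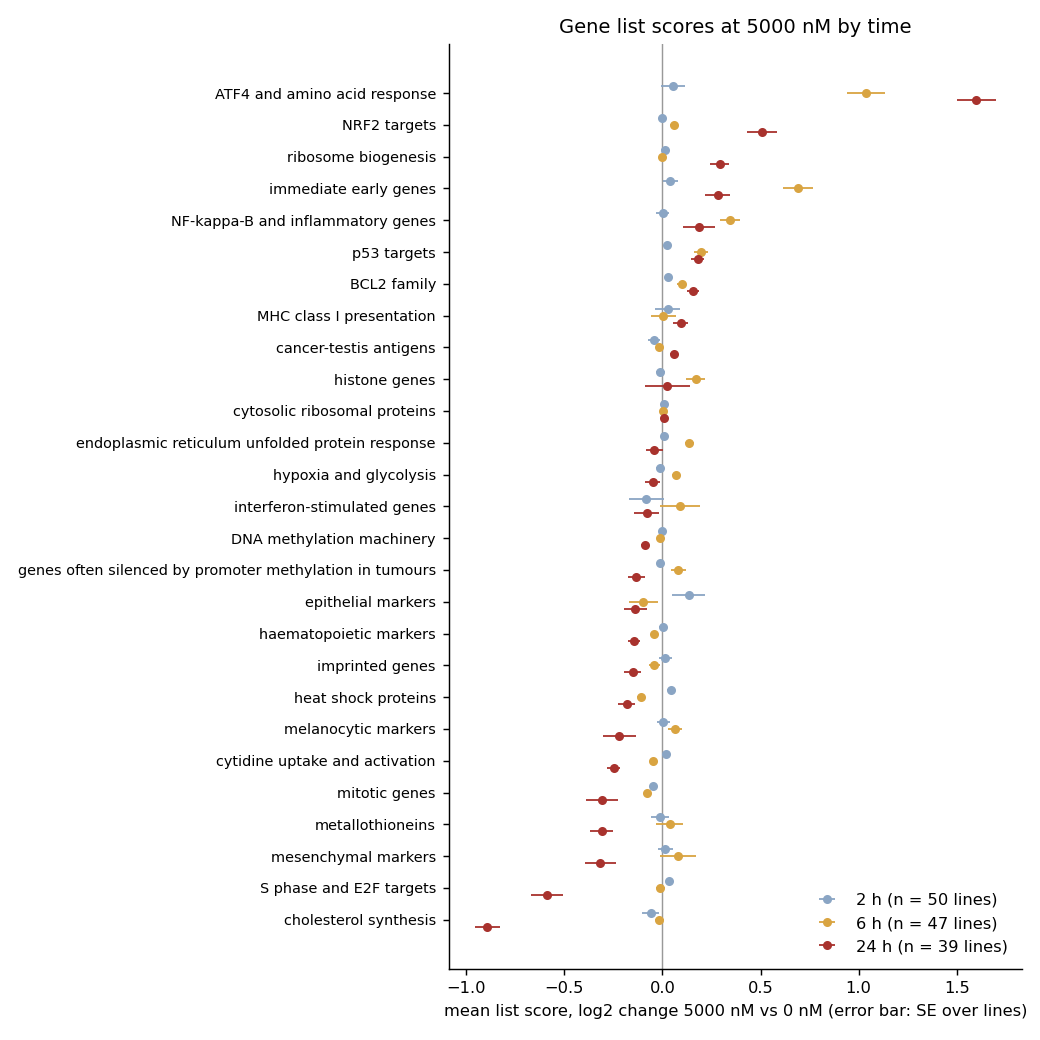
Mean list scores (log2 change, 5000 nM against 0 nM, horizontal axis) of 27 gene lists at 2 h (n = 50 lines), 6 h (n = 47) and 24 h (n = 39), with the SE over lines as error bars. At 24 h the ATF4 list is highest at 1.60 and the cholesterol synthesis list lowest at -0.89.

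At 5000 nM and 6 h genes of the stress response were already among the largest rises. ATF3 rose by 2.34 ± 1.61 (SD, n = 47), in 45 lines (adjusted p = 4.82e-11), from 6.57 to 8.91. CHAC1, which degrades glutathione, rose by 2.32 ± 1.62 (46 of 47 lines), DDIT4, an inhibitor of the growth kinase mTOR, by 2.20 ± 1.57 (45 of 47 lines), DDIT3 by 1.88 ± 1.17 (45 of 47 lines) and the immediate early factor EGR1 by 1.68 ± 1.42 (43 of 47 lines). The largest falls were smaller: GEMIN6, a part of the machinery that assembles splicing particles, fell by 0.39 ± 0.35 (40 of 47 lines), and SKP2, a ubiquitin ligase subunit of the cell cycle, fell by 0.35 ± 0.35 (41 of 47 lines). SNN, MOGS and B4GAT1 each fell by 0.34. CDKN1A rose by 0.36 ± 0.53 (40 of 47 lines), while DNMT1 (0.014, adjusted p = 0.804) did not pass. limma called 2038 genes, 907 up and 1131 down, and all 53 with at least 1.5-fold rose. With each array centred on its median, 1013 of 1813 called genes rose, 55.9% against 44.5% on the deposited scale.

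The ATF4 list rose at 5000 nM and 6 h by 1.04 ± 0.66 (45 of 47 lines, adjusted p = 8.1e-05) and the immediate early genes by 0.69 ± 0.53 (47 of 47 lines, adjusted p = 8.1e-05), and both held with an estimated correlation (adjusted p = 0.00416 and 0.00679). The NF-kappa-B and inflammatory genes rose by 0.34 ± 0.35 (40 of 47 lines, adjusted p = 8.1e-05), with adjusted p = 0.0968 with an estimated correlation. The p53 targets rose by 0.20 ± 0.24 (44 of 47 lines, adjusted p = 8.1e-05), with adjusted p = 0.571 with an estimated correlation, and 7 of 19 genes rose, also 7 adjusted over the list alone. The mitotic genes fell by 0.079 ± 0.11 (41 of 47 lines, adjusted p = 8.1e-05), with adjusted p = 0.397 with an estimated correlation, 8 of 22 genes down over all genes and 12 adjusted over the list alone. The heat shock proteins fell by 0.11 ± 0.14 (39 of 47 lines, adjusted p = 8.1e-05), with adjusted p = 0.252 with an estimated correlation. In all, 15 lists passed, 11 up and 4 down. The scores of the other 9 lay between -0.047 for cytidine uptake and activation and 0.17 for the histone genes. Each lost its call with an estimated correlation (adjusted p = 0.729 for the unfolded protein response, 0.645 for histone genes, 0.752 for the BCL2 family, 0.783 for methylation-silenced genes, 0.866 for hypoxia and glycolysis, 0.818 for melanocytic markers, 0.872 for NRF2 targets, 0.819 for cytidine uptake and 0.819 for haematopoietic markers with an estimated correlation). The NRF2 targets (adjusted p = 0.0675), cytidine uptake (adjusted p = 0.0777) and the melanocytic markers (adjusted p = 0.165) also lost their calls with the 3' to 5' signal as a covariate. For hypoxia and glycolysis the mean score was 0.067 but the mean of the line medians -0.0040, and for the NRF2 targets 0.059 but -0.0072. The BCL2 family had a mean of 0.10 and a median over its members of -0.023.

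At 1000 nM and 24 h genes of the stress and amino acid response rose and genes of cholesterol synthesis fell in most of 42 lines. ASNS rose by 1.61 ± 0.94 (SD, n = 42), in 40 lines (adjusted p = 1.98e-11), from 9.85 to 11.46. PCK2, a mitochondrial enzyme of gluconeogenesis, rose by 1.42 ± 0.99 (40 of 42 lines), NIBAN1 by 1.30 ± 1.55 (40 of 42 lines), CHAC1 by 1.22 ± 1.08 (38 of 42 lines) and CSTA, a cysteine protease inhibitor, by 1.16 ± 1.37 (37 of 42 lines). INSIG1 fell by 0.88 ± 0.74 (39 of 42 lines) and ACAT2 fell by 0.78 ± 0.63 (40 of 42 lines). LSS and MSMO1, enzymes of sterol synthesis, fell by 0.68 and 0.66, and SCD fell by 0.63. CDKN1A rose by 0.21 ± 0.44 (28 of 42 lines). limma called 2840 genes over 42 lines, 1537 up and 1303 down, and 40 changed at least 1.5-fold, 33 up and 7 down. With each array centred on its median, 1140 of 2802 called genes rose, 40.7% against 54.1%. The ATF4 list rose by 0.93 ± 0.66 (40 of 42 lines, adjusted p = 8.1e-05) and the cholesterol synthesis list fell by 0.46 ± 0.34 (37 of 42 lines, adjusted p = 8.1e-05), and both held with an estimated correlation (adjusted p = 0.0273 and 0.034). The NRF2 targets rose by 0.33 ± 0.38 (35 of 42 lines, adjusted p = 8.1e-05), adjusted p = 0.397 with an estimated correlation. In all, 15 lists passed, 8 up and 7 down, and 13 of them also passed at 5000 nM. The unfolded protein response and the ribosomal proteins passed only at 1000 nM of the 2 doses, and no list score was tested between the doses. The other 12 scores lay between -0.15 for the mitotic genes and 0.14 for the immediate early genes. They lost their calls with an estimated correlation (adjusted p = 0.742 for mitotic genes, 0.742 for S phase, 0.819 for mesenchymal markers, 0.723 for the unfolded protein response, 0.701 for cytidine uptake, 0.729 for methylation-silenced genes, 0.819 for ribosomal proteins, 0.899 for p53 targets, 0.819 for ribosome biogenesis, 0.723 for cancer-testis antigens, 0.571 for MHC class I and 0.745 for immediate early genes with an estimated correlation). The mesenchymal call was also lost with the 3' to 5' signal as a covariate (adjusted p = 0.0914).

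At 1000 nM and 6 h the changes were small and led by stress genes. DDIT3 rose by 0.47 ± 0.54 (SD, n = 51), in 41 lines (adjusted p = 2.76e-05), ATF3 by 0.42 ± 0.53 (42 of 51 lines), MAFF, a small leucine zipper factor, by 0.32 ± 0.29 (46 of 51 lines), PMAIP1 by 0.31 ± 0.38 (43 of 51 lines) and GADD45A by 0.30 ± 0.35 (47 of 51 lines). BANP, a nuclear matrix protein, fell by 0.26 ± 0.24 (47 of 51 lines), the deacetylase HDAC4 fell by 0.21 ± 0.26 (43 of 51 lines), SEC14L1 fell by 0.19, and CEPT1 and TFCP2 each fell by 0.18. limma called 586 genes over 51 lines, 270 up and 316 down, none of them by 1.5-fold. With each array centred on its median, 438 of 615 called genes rose, 71.2% against 46.1%. The ATF4 list rose by 0.22 ± 0.25 (42 of 51 lines, adjusted p = 8.1e-05) and the immediate early genes by 0.11 ± 0.10 (44 of 51 lines, adjusted p = 8.1e-05), and both held with an estimated correlation (adjusted p = 0.00679 and 0.000788). The other 5 lists that passed were the histone genes (0.061), the p53 targets (0.058), the NF-kappa-B genes (0.053), the unfolded protein response (0.039) and the heat shock proteins (-0.036), with adjusted p = 0.571 for histone genes, 0.571 for p53 targets, 0.729 for NF-kappa-B genes, 0.71 for the unfolded protein response and 0.571 for heat shock proteins with an estimated correlation. The NF-kappa-B call was lost with the 3' to 5' signal as a covariate (adjusted p = 0.0737).

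At 2 h the called genes were few, their changes small, and most of them falls. At 5000 nM THAP10, a zinc finger protein, fell by 0.33 ± 0.68 (SD, n = 50), in 44 lines (adjusted p = 0.0447). ZSCAN9 and ZNF239, zinc finger transcription factors, fell by 0.32 ± 0.42 (42 of 50 lines) and 0.28 ± 0.55 (41 of 50 lines), RSBN1, a histone demethylase, fell by 0.28 ± 0.44 (40 of 50 lines), and KMT5B, a histone methyltransferase, fell by 0.27 ± 0.39 (44 of 50 lines). The immediate early gene IER2 rose by 0.19 ± 0.36 (41 of 50 lines). At 1000 nM ZNF322 fell by 0.31 ± 0.49 (SD, n = 50), in 42 lines (adjusted p = 0.0247), RSBN1 fell by 0.30 ± 0.35 (41 of 50 lines), ZNF304 fell by 0.23, BAZ2B, a bromodomain protein, fell by 0.22 and TENT4A, an RNA poly(A) polymerase, fell by 0.20. GPR15, a chemokine receptor named here after its values were seen, was the only gene called up at 1000 nM, by 0.12 (adjusted p = 0.0454). limma called 243 genes at 5000 nM, 29 up and 214 down, and 20 at 1000 nM, 1 up and 19 down, over 50 lines each and none by 1.5-fold. At 5000 nM the split depended on the scaling: with each array centred on its median 36 of 74 called genes rose (48.6%), and after quantile normalization 28 of 120 (23.3%), against 11.9%. Without 30 arrays of high 3' to 5' signal, a mark of degraded RNA, 44 genes were called at 5000 nM over 42 lines (10 up) and 7 at 1000 nM. With that signal as a covariate 9 genes were called at 5000 nM and 1 at 1000 nM, and 0 of them rose, so IER2 and GPR15 were no longer called. Without the 23 doubted arrays, 596 and 62 genes were called.

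The mitotic genes fell at 2 h by 0.048 ± 0.073 (39 of 50 lines, adjusted p = 8.1e-05) at 5000 nM and by 0.044 ± 0.071 (42 of 50 lines, adjusted p = 0.000249) at 1000 nM, and both held with an estimated correlation (adjusted p = 0.034 and 0.0269). The 3' to 5' signal differed as well, by -0.46 at 5000 nM and -0.40 at 1000 nM (adjusted p = 0.0246 for each). With it as a covariate the mitotic score was -0.056 (adjusted p = 3.5e-05) at 5000 nM and -0.051 (adjusted p = 0.000101) at 1000 nM. At 5000 nM 5 of 22 genes fell over all genes tested, and 14 fell and 1 rose adjusted over the list alone. The heat shock proteins rose by 0.041 ± 0.11 (36 of 50 lines, adjusted p = 0.0321) and by 0.041 ± 0.10 (34 of 50 lines, adjusted p = 0.0152), with adjusted p = 0.566 and 0.571 with an estimated correlation. The S phase and E2F targets rose at 1000 nM by 0.042 ± 0.11 (33 of 50 lines, adjusted p = 0.00952), with adjusted p = 0.6 with an estimated correlation. With the covariate these heat shock and S phase calls did not hold: the heat shock proteins were at 0.012 (adjusted p = 0.551) and 0.015 (adjusted p = 0.325), and the S phase targets at 1000 nM at 0.014 (adjusted p = 0.433). The ATF4 list did not pass at 2 h, with 0.055 at 5000 nM (adjusted p = 0.597) and 0.018 at 1000 nM (adjusted p = 0.897).

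**Figure D2:**
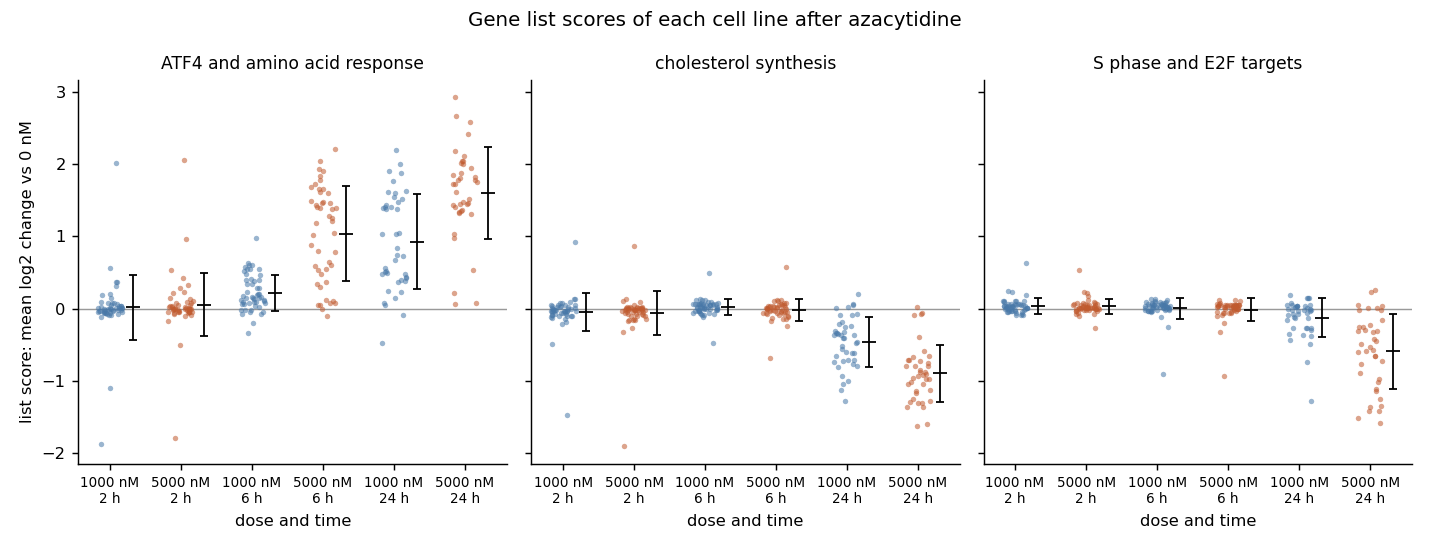
List scores (mean log2 change against 0 nM, vertical axis) of each cell line for the ATF4, cholesterol synthesis and S phase lists at each dose and time, with the mean and SD as black bars. The ATF4 scores of 39 of 39 lines lie above 0 at 5000 nM and 24 h, with minima of 0.061 among lines labelled Renal and 0.080 among lines labelled Melanoma. Both labels hold a line whose arrays at 24 h are all doubted arrays.

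The comparison of 5000 nM with 1000 nM asked whether the response depended on dose. At 24 h ATF3 was higher at 5000 nM by 1.68 ± 1.00 (SD, n = 44), in 43 lines (adjusted p = 1.48e-13), TRIB3 by 1.5 ± 1.08 (42 of 44 lines), DDIT3 by 1.43 ± 0.82 (42 of 44 lines), PPP1R15A, a phosphatase subunit that restarts translation after stress, by 1.42 ± 0.66 (43 of 44 lines) and NIBAN1 by 1.35. ID1 fell by 1.26 ± 1.02 (39 of 44 lines), NREP fell by 1.07, CYB5A fell by 1.05 ± 0.48 (44 of 44 lines), INSIG1 fell by 1.04 and SCD fell by 1.01 ± 0.63 (43 of 44 lines) between the doses. At 6 h ATF3 was higher by 1.89 ± 1.42 (SD, n = 47), in 44 lines (adjusted p = 8.6e-10), CHAC1 by 1.84, DDIT4 by 1.70, EGR1 by 1.44 and DDIT3 by 1.40. SNN fell by 0.32 ± 0.31 (42 of 47 lines), DUSP7, a phosphatase of growth kinases, fell by 0.25, SKP2 fell by 0.25, and DOLK and FZD2 each fell by 0.24. limma called 5485 genes at 24 h over 44 lines, 2734 up and 2751 down, 271 of them by at least 1.5-fold. With the 3' to 5' signal as a covariate it called 3072 at 24 h, 2972 of them shared. At 6 h it called 1736 over 47 lines, 886 up and 850 down, 35 by at least 1.5-fold. At 2 h limma called 0 genes over 49 lines, with 771 at an unadjusted p under 0.05, and called 0 under each of the 21 alternatives tried.

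Genes called at both doses were counted in the lines with all 3 doses at a time, because both comparisons use the same 0 nM arrays. At 24 h, 1239 genes such as ASNS and NIBAN1 rose at both doses, of 1423 that rose at 1000 nM and 2952 at 5000 nM, where independent lists would share 351.1. Another 1064 fell at both, of 1186 and 2838 (281 if independent). There were 15 genes called in opposite directions. Across genes, which are not independent replicates, the mean changes correlated at r = 0.840, against 0.489 in simulated unchanged groups with shared controls, and their covariance was 0.0325 against 0.00251. With each dose in separate lines, so that no 0 nM array was shared, r averaged 0.712 over 20 splits. At 6 h, 197 genes rose at both doses, of 233 and 907 (17.7 if independent). Another 185 fell, of 270 and 1131 (25.5 if independent), with r = 0.677, 0.476 simulated and 0.349 in separate lines. At 2 h, 16 genes fell at both doses, of 20 and 214, and 0 rose. Its r of 0.891 over 49 lines stood against 0.4926 simulated and 0.458 in separate lines, where on average 0.15 genes fell at 1000 nM and 5.0 at 5000 nM. The simulation gave all doses the same error. At 2 h the 3' to 5' signal varied more at 0 nM (SD 1.57) than at 1000 nM (0.87) and 5000 nM (0.67). The simulated r can therefore be too low there, and separate lines still share any shift of the 0 nM arrays.

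The difference of the 5000 nM effect between times asked whether the response grew, and was tested within lines. From 6 h to 24 h the effect on NIBAN1 grew by 2.61 ± 1.76 (SD, n = 39), in 35 lines (adjusted p = 5.18e-10), on TRIB3 by 1.76 ± 1.55 (38 of 39 lines), on LAMP3, a lysosomal protein, by 1.74 ± 1.93 (34 of 39 lines), on SERPINB8 by 1.67 and on MOCOS, a molybdenum cofactor enzyme, by 1.54. It fell by 2.10 ± 1.20 (37 of 39 lines) for INSIG1, by 1.73 ± 1.31 (35 of 39 lines) for E2F8, by 1.72 for ACAT2, by 1.67 for SCD and by 1.36 for CYB5A. From 2 h to 6 h it grew by 2.13 ± 1.87 (SD, n = 46), in 41 lines (adjusted p = 4.73e-08) for CHAC1, by 2.10 ± 1.66 (41 of 46 lines) for DDIT4, by 2.09 ± 1.77 (42 of 46 lines) for ATF3, by 1.79 for DDIT3 and by 1.60 for EGR1. It fell by 0.56 ± 1.09 (37 of 46 lines) for CDK5, a kinase, by 0.54 for MEX3D, by 0.50 for MOGS, by 0.49 for LPCAT1 and by 0.43 for LMNB2. From 2 h to 24 h the largest gains were NIBAN1 at 2.86, TRIB3 at 2.70, ATF3 at 2.46, DDIT3 at 2.27 and ASNS at 2.22. The effect fell by 1.80 for ID1, by 1.71 for INSIG1, by 1.64 for ACAT2, by 1.61 for SCD and by 1.54 for CYB5A. limma called 4457 genes between 24 h and 6 h (2426 with a higher effect at 24 h) and 5021 between 24 h and 2 h (2689 higher), both over 39 lines. Between 6 h and 2 h it called 1818 over 46 lines (1025 higher and 793 lower at 6 h). With the 3' to 5' signal as a covariate it called 784 there, 591 higher and 193 lower. The median size of the 1818 changes went from 0.25 to 0.16 with that covariate.

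Cultures at 0 nM also changed with time, which gives the background of a culture without drug. From 2 h to 24 h CCN2 and CCN1, secreted matrix proteins, fell by 1.23 ± 1.26 (40 of 44 lines) and 0.99 ± 0.90 (40 of 44 lines), MAFF fell by 0.97, ATF3 fell by 0.95 ± 1.06 (SD, n = 44), in 38 lines (adjusted p = 5.98e-05) and KLF11, a zinc finger repressor, fell by 0.89 ± 0.56 (42 of 44 lines). DDIT4 rose by 1.12 ± 1.59 (36 of 44 lines), TECR, an enzyme of fatty acid elongation, by 0.73 ± 1.15 (39 of 44 lines), GPI by 0.66, AGBL5 by 0.65 and MEN1 by 0.61. From 2 h to 6 h CCN2 fell by 0.92 ± 1.32 (43 of 52 lines), ATF3 fell by 0.85, KLF11 fell by 0.84, PTGER4, a prostaglandin receptor, fell by 0.73 and SMAD7 fell by 0.72. HMG20B rose by 0.66, TUBD1 by 0.53, DDIT4 by 0.50, TOB2 by 0.49 and AKT1 by 0.47. limma called 2186 genes at 6 h (1153 up, 52 lines) and 1364 at 24 h (697 up, 44 lines). With each array centred on its median, 809 of 2093 rose at 6 h (38.7% against 52.7%) and 423 of 1471 at 24 h (28.8% against 51.1%). With the 3' to 5' signal as a covariate 1061 genes were called at 6 h and 1050 at 24 h. In the 0 nM arrays at 2 h the mean 3' to 5' signal was highest, with 8 of the 30 arrays of high 3' to 5' signal.

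The test across tissue labels asked whether the 5000 nM response at 24 h depended on the tissue of origin. No gene passed it. DOCK2, a guanine exchange factor of blood cells, came closest (limma F = 7.93, adjusted p = 0.0744), then SLC6A15, an amino acid carrier (adjusted p = 0.0958), and PPP2R2B, a phosphatase subunit (adjusted p = 0.245). MCMBP and CDCP1 both had an adjusted p of 0.460, and TRAF1, CD14 and PPP1R3C one of 0.468. limma called 0 of 11963 genes over 39 lines with 9 tissue labels, with 709 at an unadjusted p under 0.05. No list score passed the test between tissue labels after adjustment: the lowest permutation p was 0.0215, for the DNA methylation machinery (42.1% of the variance between tissues, adjusted p = 0.58). The Colon and Prostate labels held only 2 lines each here. The labels themselves are a limit, because 0 of the 5 lines labelled Leukemia were among the 8 lines highest in haematopoietic markers such as PTPRC, CD53 and LCP1. Of the 9 labelled Melanoma, 1 was among the 8 highest in melanocytic markers such as MLANA and TYR, and its 0 nM arrays disagreed by 6.22 in that level.

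**Figure D3:**
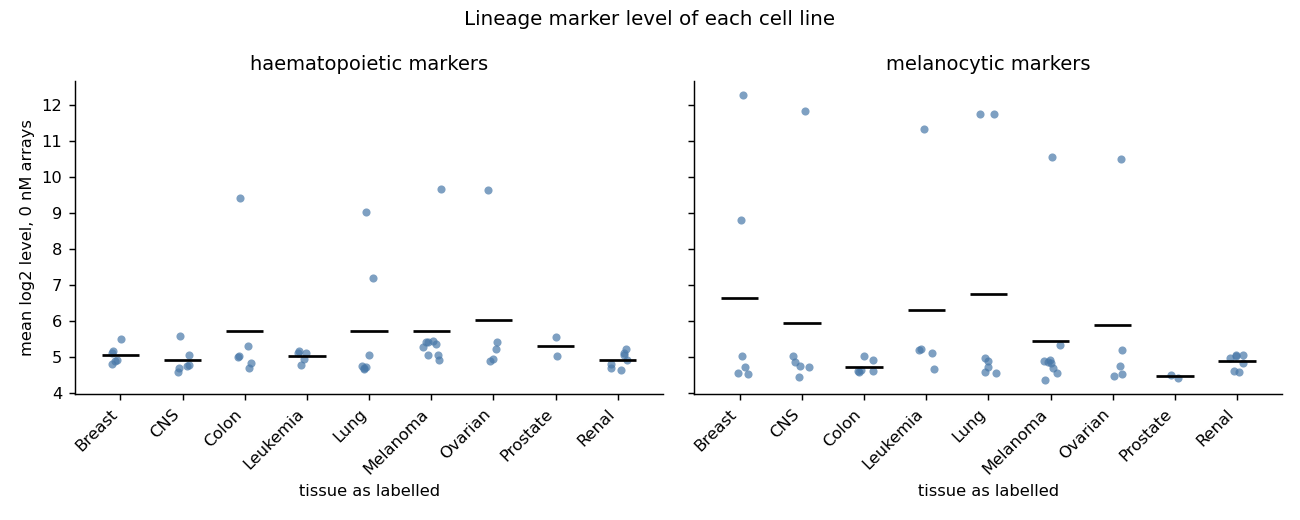
Mean log2 level of haematopoietic and of melanocytic markers in the 0 nM arrays of each cell line (points), by tissue label, with the mean of each label as a bar. Lines labelled Leukemia reach at most 5.15 in haematopoietic markers, where the highest line is at 9.67.

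Baseline levels at 2 h of 0 nM were set against the 24 h response to 5000 nM over 39 lines, to ask whether uptake, activation or target genes went with the response. The response was read as the p53 target list score and as a signature score, the slope of a line's changes on the mean changes of the other lines, which averaged 0.95 ± 0.34 (SD) and ranged from -0.0093 to 1.41. The strongest relation was that of DNMT3B, a de novo methyltransferase, with the p53 score (r = 0.28, permutation p = 0.0799, rho = 0.27, p = 0.101, adjusted p = 0.991). Without the 2 lines farthest from the median baseline its r was 0.17 (p = 0.326, n = 37). Without doubted arrays SLC29A1 came first with the p53 score (r = 0.36, p = 0.0377, adjusted p = 0.422, n = 33), against 0.22 with all arrays, and DNMT3B had r = 0.34 (p = 0.0527). None of the 16 relations passed, with SLC29A1, CDA, DCK, DNMT1, DNMT3B, TRDMT1, RRM2 and the mean of the S phase list as baselines and r between -0.10 and 0.28 over all arrays. None passed within tissue labels either, after the tissue means were removed (smallest adjusted p = 0.846).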

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

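The tests of the line and tissue labels, of a mixture of cells, of an early response and of a few arrays of high 3' to 5' signal were chosen only after the result was seen, while the random regroupings were set before. The fit with RNA integrity as a covariate was set when the 243 genes called at 5000 nM and 2 h were known and its own result was not. The effect of 5000 nM differed between times by a test within lines, in 4457 genes between 24 h and 6 h, NIBAN1 and INSIG1 among them. It differed in 5021 genes between 24 h and 2 h, and in 1818 between 6 h and 2 h, CHAC1 and DDIT4 among these. Chance is argued against for each: the highest of the other exchanges of arrays within lines gave 1124, 1722 and 2 genes. Of 100 exchanges 1, the real one, gave as many, the smallest share they can give. With the 3' to 5' signal as a covariate 4492, 4361 and 784 genes were called.

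At 5000 nM, 240 genes were called in opposite directions at 6 h and 24 h with a called difference between the times, of 1437 genes called at both, and 47 of the 240 rose at 6 h. The score of the genes often silenced by promoter methylation in tumours was 0.080 at 6 h and -0.13 at 24 h, a difference of -0.21 (adjusted p = 0.00135, n = 39). The score of the melanocytic markers was 0.065 at 6 h and -0.22 at 24 h, a difference of -0.29 (adjusted p = 0.00461, n = 39). Neither list passed camera with an estimated correlation, which sets a list against the other genes. For the methylation-silenced genes its adjusted p was 0.783 at 6 h, 0.818 at 24 h and 0.532 for the difference. For the melanocytic markers it was 0.818, 0.819 and 0.698. With the 3' to 5' signal as a covariate the melanocytic calls were lost at 6 h and at 24 h (adjusted p = 0.165 for each), and those of the methylation-silenced genes held (adjusted p = 0.0244 and 0.017). The opposite directions of the melanocytic markers are therefore not secure. Those of the methylation-silenced genes passed against 0 but not against the other genes, and their 24 h call was lost in some alternatives below.

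Probe sets without a single gene symbol lie outside the comparisons of genes, and 1113 of 3151 (35.3%) were called at 5000 nM and 24 h against 0 nM. Of these, 554 rose and 132 changed at least 1.5-fold. The ATF4, cholesterol synthesis and S phase scores at 5000 nM and 24 h were also searched for a line that lay outside others of its tissue label. This gave 21 sets of a score and a label. None was found, where chance marks about 1 in 20 sets. With few lines per label the search can miss a line. It marked neither the ATF4 score of 0.061 (Renal, mean 1.31, SD 0.83) nor that of 0.080 (Melanoma, mean 1.42, SD 0.69).

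The first pattern is that lineage markers did not follow the tissue labels. Haematopoietic markers averaged 5.02 (SD 0.16) in the 5 lines labelled Leukemia and 5.43 (SD 1.29) in the other lines, and 0 of these 5 lines were among the 8 highest. Of the 9 lines labelled Melanoma, 1 was among the 8 highest in melanocytic markers. That line, UACC-257, has a median of 10.55 over 0 nM arrays that differ by 6.22 in this level, and its 0 nM arrays at 2 h and 24 h are doubted arrays, so this count rests on arrays that disagree. The tested count, 0 of 5, cannot decide on a mislabelled sample or tissue label, because it is the pattern itself. No separate test of the tissue labels was made. The 8 lines highest in melanocytic markers, at 8.81 to 12.27, were labelled Breast (2), Lung (2), CNS (1), Leukemia (1), Melanoma (1) and Ovarian (1). In the 5 lines with the highest haematopoietic level, ARHGDIB was at 11.41 (SD 1.53), CD53 at 9.98, LCP1 at 9.69 and PTPRC at 9.33, against 6.39, 4.57, 5.77 and 4.08 in the other 48 lines, and SPN was not raised (4.63 against 4.59). In these 5 lines a mixture with haematopoietic cells cannot be told apart from a wrong label. The higher of the epithelial and mesenchymal levels averaged 6.21 there against 9.27 (SD 1.70) elsewhere, -1.80 SD. Its values were 5.38 to 7.49 against 6.23 to 12.64, and no sort or gate is stated. A mixture adds haematopoietic markers, yet the lines labelled Leukemia reached at most 5.15, against 9.67 in the highest line. These values argue against a mixture as the cause in the lines labelled Leukemia. No biological explanation was tested. The null result of the tissue test rests on these labels.

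Another pattern is a pair of line labels, UACC-257 and a line labelled Renal, whose signature score at 5000 nM was -0.0093 and 0.0016 at 24 h, against 0.31 or more in the other 37 lines. Both had a high score earlier, UACC-257 with 1.18 at 2 h, from arrays that are doubted too, and the line labelled Renal with 1.25 at 6 h. All 6 arrays labelled with these lines at 24 h matched another line label best, which is consistent with mislabelled samples. An early response of the line that ended by 24 h would leave its arrays matching their own label. The 6 arrays correlated with the other arrays of their label at 0.16 to 0.58, with a median of 0.389. The lowest of the 417 arrays not doubted was at 0.71, but these were kept for matching their own label, so that bound is no independent measure. Each of the 6 reached 0.91 or more with another label, which argues against that explanation for the 6 arrays. As all 6 are doubted arrays, they do not show what these lines did at 24 h. Whether an early response had ended in the lines themselves cannot be told. With every doubted array left out, ATF4 list scores at 5000 nM and 24 h averaged 1.66 against 1.60.

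A further pattern is the set of 243 genes called at 5000 nM and 2 h, such as RSBN1 and KMT5B, of which 214 fell. Arrays at 0 nM and 2 h had a higher 3' to 5' signal: the mean difference of treated from 0 nM arrays was -0.46 (SD 1.23, n = 50, permutation p = 0.00861, adjusted p = 0.0246), with a median of -0.0012. With this difference as a covariate, 9 genes were called and 0 of them rose, so a difference in RNA integrity is not excluded as the whole cause. The median of the 214 falling genes went from -0.16 (SD 0.05 over genes) to -0.11 (SD 0.04) and the median SE from 0.0395 to 0.0362, so the calls ended because the changes shrank. The falls shrank but did not reach 0, and with the covariate 1007 genes kept an unadjusted limma p under 0.05. The 214 genes were picked for falling in these same arrays, so their remaining fall does not settle the cause. The covariate was related to 5098 genes. When the arrays of high 3' to 5' signal were left out, 44 genes were called, 28 of them shared. This argues against a few such arrays as the whole cause for those 28 genes. The highest other regrouping gave 1, but it used all arrays, and none was run without those of high signal. Arrays with a 3' signal raised by less than 1 stayed in, so smaller differences in RNA integrity were not covered. An early effect of azacytidine stays open beside RNA integrity.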

How the results depend on the processing

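The comparisons without doubted arrays, without arrays of high 3' to 5' signal and with that signal as a covariate were chosen after the data were seen, and the other alternatives before. Counts of called genes were recomputed 319 times, and 257 stayed within 1.5 times the reported count. The count at 5000 nM and 24 h ranged from 1932 to 6548, that at 1000 nM and 24 h from 28 to 2942, and that at 5000 nM and 6 h from 32 to 2673. The count for 5000 nM against 1000 nM at 2 h was 0 in all 21 alternatives. Of 3552 recomputed list scores, 3193 kept their direction and their side of the threshold, 291 lost their call, 63 gained a call and 5 reversed. Of 5614 recomputed changes of named genes, 5295 kept both, 299 lost their call and 20 gained one, and none reversed. All 64 recomputed baseline relations stayed uncalled. A change of sign in a score or gene uncalled both times, 242 in all, was counted as no change. Except where a reason is given, the cause was not tested.

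Without pairing by line, the differences between lines enter the error, and fewer genes were called. There were 0 for 1000 nM at 2 h, 0 for 5000 nM at 2 h, 0 for 1000 nM at 6 h, 32 for 5000 nM at 6 h, 28 for 1000 nM at 24 h and 1932 for 5000 nM at 24 h. There were 11 for 5000 against 1000 nM at 6 h, 780 for 5000 against 1000 nM at 24 h, 814 for the effect at 24 h against 2 h, 411 for the effect at 24 h against 6 h, 8 for the effect at 6 h against 2 h, 2 for 0 nM at 6 h and 6 for 0 nM at 24 h. At an adjusted p under 0.01, stricter by construction, limma called 4 for 1000 nM at 2 h, 37 for 5000 nM at 2 h, 289 for 1000 nM at 6 h, 1247 for 5000 nM at 6 h, 1772 for 1000 nM at 24 h, 1036 for 5000 against 1000 nM at 6 h, 904 for the effect at 6 h against 2 h, 982 for 0 nM at 6 h and 577 for 0 nM at 24 h, where the 4 were BORA, RNF111, RSBN1 and TENT4A. With 3 doses in a fit with a replicate block it called 250 for 1000 nM at 2 h and 920 for 5000 nM at 2 h, a fit that pools the error of all doses. With array median centring it called 10 for 1000 nM at 2 h, 74 for 5000 nM at 2 h and 8 for both doses at 2 h, and with quantile normalisation 120 for 5000 nM at 2 h and 10 for both doses at 2 h. Among the upper genes by mean level it called 74 for 1000 nM at 2 h and 403 for 5000 nM at 2 h. In lines with all 9 arrays, fewer by construction, it called 12 for 1000 nM at 2 h, 89 for 5000 nM at 2 h and 213 for 1000 nM at 6 h. The cause of the changes with the scaling and the level was not tested.

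Leaving out a tissue label changed mainly the counts at 2 h. Lineage markers did not follow these labels (0 of 5 lines labelled Leukemia and 1 of 9 labelled Melanoma were among the 8 highest), so the lines left out, here and in the list scores below, are those with a label and are not shown to be of that tissue. Without Breast lines limma called 121 for 5000 nM at 2 h and 1 for the tissue test. Without CNS lines limma called 5 for 1000 nM at 2 h, 64 for 5000 nM at 2 h and 858 for 0 nM at 24 h. Without Leukemia lines limma called 3 for 1000 nM at 2 h and 65 for 5000 nM at 2 h. Without Lung lines limma called 9 for 1000 nM at 2 h and 105 for 5000 nM at 2 h. Without Melanoma lines limma called 2 for 1000 nM at 2 h. Without Ovarian lines limma called 12 for 1000 nM at 2 h and 96 for 5000 nM at 2 h. The genes at 1000 nM and 2 h were BORA, RNF111, RSBN1, TENT4A and ZBED5 without CNS, BORA, RSBN1 and TENT4A without Leukemia, and RNF111 and RSBN1 without Melanoma. In the tissue test the gene called was PPP2R2B without Breast, DOCK2 with the trend and robust prior (1 for the tissue test) and MCMBP without doubted arrays. Without doubted arrays limma called 62 for 1000 nM at 2 h, 596 for 5000 nM at 2 h, 917 for 1000 nM at 6 h, 2087 for 0 nM at 24 h, 1 for the tissue test, 52 for both doses at 2 h and 608 for both doses at 6 h. Without arrays of high 3' to 5' signal it called 7 for 1000 nM at 2 h, 44 for 5000 nM at 2 h and 1076 for the effect at 6 h against 2 h. With that signal as a covariate it called 1 for 1000 nM at 2 h, 9 for 5000 nM at 2 h, 3072 for 5000 against 1000 nM at 24 h, 784 for the effect at 6 h against 2 h and 1061 for 0 nM at 6 h, where the gene at 1000 nM was RSBN1. The genes of these small counts that the naming rule leaves out were chosen after their values were seen, and the cause was not tested.

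The rest concerns list scores at 5000 nM and 24 h. With camera, which sets a list against the other genes, the adjusted p at the preset correlation was 0.5504 for p53 targets, 0.507 for MHC class I, 0.559 for cancer-testis, 0.458 for methylation-silenced genes, 0.559 for imprinted genes, 0.545 for heat shock proteins, 0.101 for immediate early, 0.637 for BCL2 family, 0.559 for methylation machinery, 0.111 for cytidine uptake, 0.423 for melanocytic, 0.604 for haematopoietic and 0.196 for mesenchymal. At the estimated correlation it was 0.836 for p53 targets, 0.586 for S phase, 0.819 for mitotic genes, 0.836 for MHC class I, 0.836 for cancer-testis, 0.818 for methylation-silenced genes, 0.819 for imprinted genes, 0.731 for metallothioneins, 0.0540 for ATF4 and 0.836 for heat shock proteins. For the other lists it was 0.752 for immediate early, 0.742 for ribosome biogenesis, 0.137 for cholesterol synthesis, 0.729 for NRF2 targets, 0.819 for BCL2 family, 0.819 for methylation machinery, 0.586 for cytidine uptake, 0.819 for melanocytic, 0.819 for haematopoietic and 0.814 for mesenchymal. Over all alternatives the adjusted p ranged from 3.24e-09 to 0.836 for p53 targets, 5.9e-12 to 0.586 for S phase, 2.28e-05 to 0.819 for mitotic genes, 0.00753 to 0.999 for MHC class I, 0.00958 to 0.999 for cancer-testis, 0.000268 to 0.999 for methylation-silenced genes and 6.52e-05 to 0.999 for imprinted genes. It ranged from 6.06e-06 to 0.999 for metallothioneins, 1.63e-24 to 0.054 for ATF4, 1.61e-06 to 0.836 for heat shock proteins, 1.18e-06 to 0.752 for immediate early, 3.57e-10 to 0.742 for ribosome biogenesis, 1.74e-24 to 0.137 for cholesterol synthesis and 2.5e-10 to 0.729 for NRF2 targets. For the rest it ranged from 3.2e-08 to 0.819 for BCL2 family, 6.1e-06 to 0.819 for methylation machinery, 2.08e-13 to 0.586 for cytidine uptake, 0.00358 to 0.999 for melanocytic, 2.35e-05 to 0.999 for haematopoietic and 5.1e-06 to 0.999 for mesenchymal.

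Without pairing by line, scores have the same mean by construction but a larger error, and calls were lost for p53 targets, MHC class I, cancer-testis, methylation-silenced genes, imprinted genes, metallothioneins, heat shock proteins, immediate early, NRF2 targets, BCL2 family, methylation machinery, melanocytic, haematopoietic and mesenchymal, with scores of 0.18, 0.093, 0.059, -0.13, -0.15, -0.31, -0.18, 0.28, 0.51, 0.16, -0.088, -0.22, -0.14, -0.32. With the median over the list's genes, calls were lost at -0.087 for imprinted genes, -0.23 for melanocytic and -0.056 for haematopoietic, and gained at -0.14 for hypoxia.

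With quantile normalization, calls were gained at 0.019 for ribosomal proteins. With array median centring, calls were lost at 0.059 for cancer-testis and gained at -0.14 for epithelial. Among the upper genes by mean level, calls were lost at 0.028 for cancer-testis and -0.10 for methylation-silenced genes and gained at -0.27 for epithelial. With the mean of a gene's probe sets, calls were lost at 0.068 for MHC class I and -0.037 for methylation-silenced genes and gained at -0.091 for hypoxia. With 3 doses in a fit, calls were gained at 0.20 for NF-kappa-B and -0.14 for epithelial. Without Breast lines, calls were lost at 0.051 for cancer-testis and -0.20 for melanocytic. Without CNS lines, calls were lost at 0.051 for cancer-testis. Without Colon lines, calls were lost at 0.057 for cancer-testis. Without Leukemia lines, calls were lost at 0.093 for MHC class I and gained at 0.20 for NF-kappa-B. Without Lung lines, calls were lost at 0.081 for MHC class I and 0.057 for cancer-testis. Without Melanoma lines, calls were lost at 0.094 for MHC class I and 0.057 for cancer-testis and gained at -0.19 for epithelial. Without Ovarian lines, calls were lost at 0.082 for MHC class I, 0.057 for cancer-testis and -0.17 for melanocytic and gained at -0.16 for epithelial. Without Prostate lines, calls were lost at 0.050 for cancer-testis and gained at -0.15 for epithelial. Without Renal lines, calls were lost at 0.080 for MHC class I, -0.11 for methylation-silenced genes and -0.22 for melanocytic and gained at -0.16 for interferon genes. Without doubted arrays, calls were lost at 0.059 for cancer-testis. With the 3' to 5' signal as a covariate, calls were lost at 0.10 for MHC class I, 0.029 for cancer-testis, -0.12 for heat shock proteins and -0.19 for melanocytic. The cause was not tested for any of these.

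Scores at 5000 nM and 6 h that reversed were MHC class I, 0.0053 and uncalled as reported, which was -0.057 without Leukemia lines, -0.046 without doubted arrays and -0.055 without arrays of high 3' to 5' signal. With the median over the list's genes, hypoxia went from 0.067 to -0.0040 and the NRF2 targets from 0.059 to -0.0072, both then uncalled. The ATF4 score at 24 h kept its sign and lay between 1.47 and 1.66 in every alternative, and the cholesterol synthesis score between -0.97 and -0.77. Signals near the array's background limit what can be seen: the lower quartile of the signals was 4.32, where a change is compressed.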

Other observations

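The gene groups of the hypotheses below were chosen only after the result was seen, and the random regroupings were set before. Lines are the units that were regrouped, by exchanging the arrays of randomly chosen lines, in 100 regroupings that include the real one. Chance is argued against for the 13 counts of called genes above 0, where 1 of 100, the real one, gave as many. That is the smallest share 100 regroupings can give, and it was not adjusted over the 13 counts. The regroupings do not bear on RNA integrity: with the 3' to 5' signal as a covariate, 1 gene at 1000 nM and 9 at 5000 nM were called at 2 h. The real count and the highest of the others were 20 against 1 at 1000 nM and 2 h, 243 against 1 at 5000 nM and 2 h, 586 against 1 at 1000 nM and 6 h, 2038 against 34 at 5000 nM and 6 h, 2840 against 148 at 1000 nM and 24 h and 5790 against 1506 at 5000 nM and 24 h. They were 1736 against 0 between the doses at 6 h, 5485 against 1447 between the doses at 24 h, 2186 against 2 in 0 nM cultures at 6 h and 1364 against 0 at 24 h. For 5000 nM against 1000 nM at 2 h, where limma called 0 genes and 771 had an unadjusted p under 0.05, a regrouping cannot give fewer, so the 100 regroupings decide nothing, and the highest other gave 2. The same holds for the tissue test, where limma called 0 genes, 709 had an unadjusted p under 0.05, and the highest of the other labellings gave 15.

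A first hypothesis was that lines with a higher ATF4 list score at 6 h also had a higher one at 24 h, at 5000 nM. The test gave r = 0.029 over 39 lines (permutation p = 0.865, rho = -0.14, p = 0.413). Without the 2 lines farthest from the median, r was -0.22 (p = 0.198, n = 37), and without lines with doubted arrays it was -0.049 (p = 0.793, n = 31). No such relation was found.

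A second hypothesis was that cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs and are targets of ATF4, rose together at 5000 nM and 24 h. Their mean score was 0.61 ± 0.25 (SD, n = 39, above 0 in 37 lines, permutation p = 1e-05, the smallest they can give), with a camera p of 0.00931 with an estimated correlation. Of 16 genes 14 rose, WARS1 by 1.53 ± 0.60, SARS1 by 1.21 ± 0.44 and CARS1 by 1.19 ± 0.50, and LARS1 fell by 0.29 ± 0.46. VARS1 did not pass (-0.096, adjusted p = 0.229). At 1000 nM and 24 h the score was 0.32 ± 0.21 (n = 42). These values are consistent with a shared rise of the synthetases, found and tested on the same data.

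Another hypothesis was that genes named ZNF, zinc finger genes, were over-represented among the genes that fell at 5000 nM and 2 h. Of 235 such genes 18 fell, against 196 of 11728 others, an odds ratio of 4.88 (Fisher's exact test, p = 2.16e-07). Without doubted arrays 33 of 235 fell, against 493 of the others (odds ratio 3.72, p = 2.99e-09). Without arrays of high 3' to 5' signal 1 of 235 fell, against 33 of the others (odds ratio 1.51, p = 0.491), so few falls were left to test. The median change of the ZNF genes was then -0.026 (SD 0.061 over genes) and that of the others -0.0034. With array median centring 2 of 235 fell, against 36 of the others (odds ratio 2.79, p = 0.171). The hypothesis stays open, and RNA integrity or the scaling could lie behind it. At 5000 nM and 24 h ZNF genes were under-represented among the falls (odds ratio 0.1998, Fisher's exact test, p = 3.01e-13). Genes are not independent replicates, so the p-values of Fisher's exact test here do not measure chance over lines.

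Some line labels had signature scores far from the others. K-562 had -1.12 at 1000 nM and -1.13 at 5000 nM at 2 h, where the next lowest lines had -0.14 and -0.11. Both scores rest on its 0 nM array at 2 h, a doubted array, whose correlation with the other arrays of its label was -0.043, and whose 3' to 5' signal was 4.59. MOLT-4 had -0.29 at 1000 nM and 24 h and 0.31 at 5000 nM and 24 h. Its 3 arrays at 24 h matched their own label best (correlations of 0.86 to 0.94), while its 0 nM array at 6 h is a doubted array (-0.0086).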
